A study of Mus musculus with 2 samples.

How the data were processed

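H3K27me3 chromatin immunoprecipitation sequencing was done on 2 pools of mouse embryonic facial prominence of embryonic day 14.5, biological replicates of 1 group by the labels. The labels state the numbers of embryos pooled, 24 and 34, and that both sexes were mixed. Of 4 peak lists, 1 came from each replicate, 1 from both replicates' alignments together (pooled peaks) and 1 was the list of replicated peaks, per the descriptions deposited with the files. Coordinates are on mm10, per the labels. The aligner, peak caller, thresholds, any filter of problem regions and the rule behind the replicated list are not given in the sources used here. The descriptions list 1 further input file for replicate 1 and 2 for replicate 2 without stating their roles.

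Each peak carries an enrichment signal value as deposited by the authors, whose exact definition is not stated, so it is not called a fold here. Each also carries the −log10 of a p and of a q as deposited by the authors' caller. These values were used only to describe, rank or filter peaks within their own list. No read numbers were given, so depth is unknown and no counting intervals could be made. A list from a deeper library holds more weak peaks, and a caller of narrow peaks splits broad domains, which affects peak counts more than covered bases.

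The reference was GRCm38.p6, the same build, with GENCODE annotation M21. All peak ends lay within its chromosome lengths. Protein-coding genes on chromosomes 1 to 19 and X were used, 21728 after 27 repeated symbols were dropped, with 93111 transcript starts. A promoter was the most upstream annotated start with 1 kb on each side, and it was marked when peaks covered at least 25% of it. CpG-rich promoters had a CpG observed/expected ratio of at least 0.6 and a GC share of at least 50%. Domains were replicated peaks joined at gaps of up to 5 kb, and wide domains were at least 20 kb. Peaks were shared when at least 50% of the peak was covered.

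Overlap, marked genes and genomic context were tested against 100 circular shifts along each chromosome, and for context each peak list was set against shifts of itself. CpG content was tested with 100000 permutations over promoters. The 20 gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment, and set beside 10000 random lists matched on CpG content. The lists held 549 genes, of which 548 were in the annotation (Ezhip was missing) and 36 were in more than 1 list. Lists, tests, thresholds and most alternatives were fixed before the data were examined. The 6 comparisons between lists, with shared members removed, were added after that, before the lists' results were computed. The replicates' spread is given as mean ± SD with n = 2, and with 1 group no test between groups was possible.

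Genes named in the text follow a rule fixed beforehand. From each list it takes the 3 marked members with the largest coverage of the promoter window with 10 kb on each side (22 kb), and up to 3 unmarked members in symbol order where under 90% were marked. It adds the 10 widest domains, the 5 peaks of highest enrichment value, and Ezh2, Eed, Suz12, Actb and Gapdh. Genes named outside this rule were chosen after their values were seen: Neurod4, Neurod6, Pcgf5, Phf19, Acan, Comp, Col2a1, Col1a2, Col9a1 and those of the closing section.

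Alternatives were a stricter −log10 q, other overlaps, windows, coverage thresholds, starts and gaps, pooled peaks, each replicate alone, and CpG-rich promoters alone. The functions were tested on simulated data before use. In peaks shifted at random, with a peak added at 200 of 21728 promoters, 100.0% of these promoters were called marked and 1.46% of the others. All 5 simulated enriched lists and 0 of 15 unchanged lists were called. The added peaks were centred on the starts and wide enough to pass the threshold by design. The unchanged lists were random genes at a lower marked share than the 12.7% in the real data. The simulation therefore checked the code, and not the power or the rate of false calls of the real tests. When 30.1% of replicate 1 peaks were copied into a second list, 30.6% were found shared. The work used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and Matplotlib 3.10.9.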

Results

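H3K27me3, the trimethylated lysine 27 of histone H3 that Polycomb repressive complex 2 deposits, was profiled by chromatin immunoprecipitation and sequencing in the embryonic facial prominence of B6 mice at embryonic day 14.5. The facial prominences are the outgrowths that form the jaws, nose and palate. The samples formed 1 group of 2 biological replicates, pools of facial prominence from 24 embryos (replicate 1) and 34 embryos (replicate 2), each of both sexes. There was no second tissue, age or mark, so no groups could be compared. The comparisons were those between the replicates, between sets of genes and between parts of the genome. Read numbers were not given, so the depth behind each peak is unknown.

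H3K27me3 peaks covered 25.81 Mb in replicate 1 and 26.84 Mb in replicate 2, a mean of 26.32 ± 0.726 Mb (SD, n = 2), or 0.98% and 1.02% of chromosomes 1 to 19 and X. Strong peaks were shared between the pools and weak peaks often were not. Of replicate 1 peaks with a −log10 q of at least 10, 99.7% were covered over at least 50% of their length by replicate 2 peaks, against 19.1% of those with a −log10 q under 2. The corresponding shares of replicate 2 peaks were 98.7% and 16.4%. The strong peaks were also wider, with median widths of 2147 bp against 219 bp in replicate 1 and 2066 bp against 221 bp in replicate 2. Strength and width were not separated. Over all peaks, 36.2% of 58406 in replicate 1 and 33.4% of 57179 in replicate 2 were shared. After circular shifts of the other list along each chromosome, the highest shares in 100 shifts were 1.66% and 1.59% (one-sided permutation p = 0.0099 for each, the smallest that 100 shifts can give).

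The deposited list of replicated peaks held 22275 regions over 25.16 Mb, with a median width of 611 bp. Each had the coordinates of a peak called on both replicates together, and they were 26.5% of those 84039 pooled peaks and 59.8% of their bases. Among pooled peaks with a −log10 q of at least 2 the share kept was 40.4%. All 18261 pooled peaks that shared at least 50% of either peak with a peak of each replicate were in the list. The other 4014 replicated peaks (18%) lacked that overlap and were narrower, with a median width of 438 bp against 690 bp.

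Promoters of 2757 of 21728 protein-coding genes (12.7%) were marked, meaning that replicated peaks covered at least 25% of the 2 kb around the gene's most upstream annotated start. Replicate 1 peaks marked 2465 genes and replicate 2 peaks 2654, a mean of 2560 ± 134 (SD, n = 2). Both replicates marked 2256 genes, against 301 expected for independent lists. Shifted replicated peaks marked at most 351 genes (one-sided permutation p = 0.0099, the smallest possible). Marked promoters were richer in CpG dinucleotides, with a median observed/expected ratio of 0.564 against 0.447 at unmarked promoters, and in G and C, at 56.3% against 50.3% (two-sided permutation p = 1e-05 for each, the smallest possible). Of CpG-rich promoters 17.1% were marked, and of the others 10.8%. Windows of 1 kb on each side of any annotated protein-coding start held 25.6% of replicated peak bases, 6.59 times the mean of the shifted lists. Exons outside those windows held 6.91% against 2.74% in shifted lists. Introns held 28.6% against 34.5% and intergenic sequence 38.9% against 58.9% (two-sided permutation p = 0.0198 for each of the 4 contexts, the smallest possible). Introns held 31.3% of the bases of pooled peaks, against a mean of 33.4% after shifts of the pooled peaks, and this did not pass (two-sided permutation p = 0.0792).

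All 39 Hox genes, which pattern the trunk and limbs, were marked in the replicated list and by the peaks of each replicate (Fisher's exact adjusted p = 8.53e-35). The mark lay over whole clusters. Between the outermost Hox starts, replicated peaks covered 98.2% of HoxA (chromosome 6, 52155590 to 52260880, mm10), 83.1% of HoxB (chromosome 11, 96194316 to 96368256), 99.2% of HoxC (chromosome 15, 102921103 to 103036852) and 97.8% of HoxD (chromosome 2, 74668310 to 74765142). Coverage by the replicates' own peaks was 93.9 ± 0.256%, 79.7 ± 1.74%, 96.5 ± 0.591% and 93.6 ± 1.35% in that order (SD, n = 2). The promoter windows of Hoxa3, Hoxa4 and Hoxa5 and the 10 kb on each side were covered completely by replicated peaks.

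**Figure D1:**
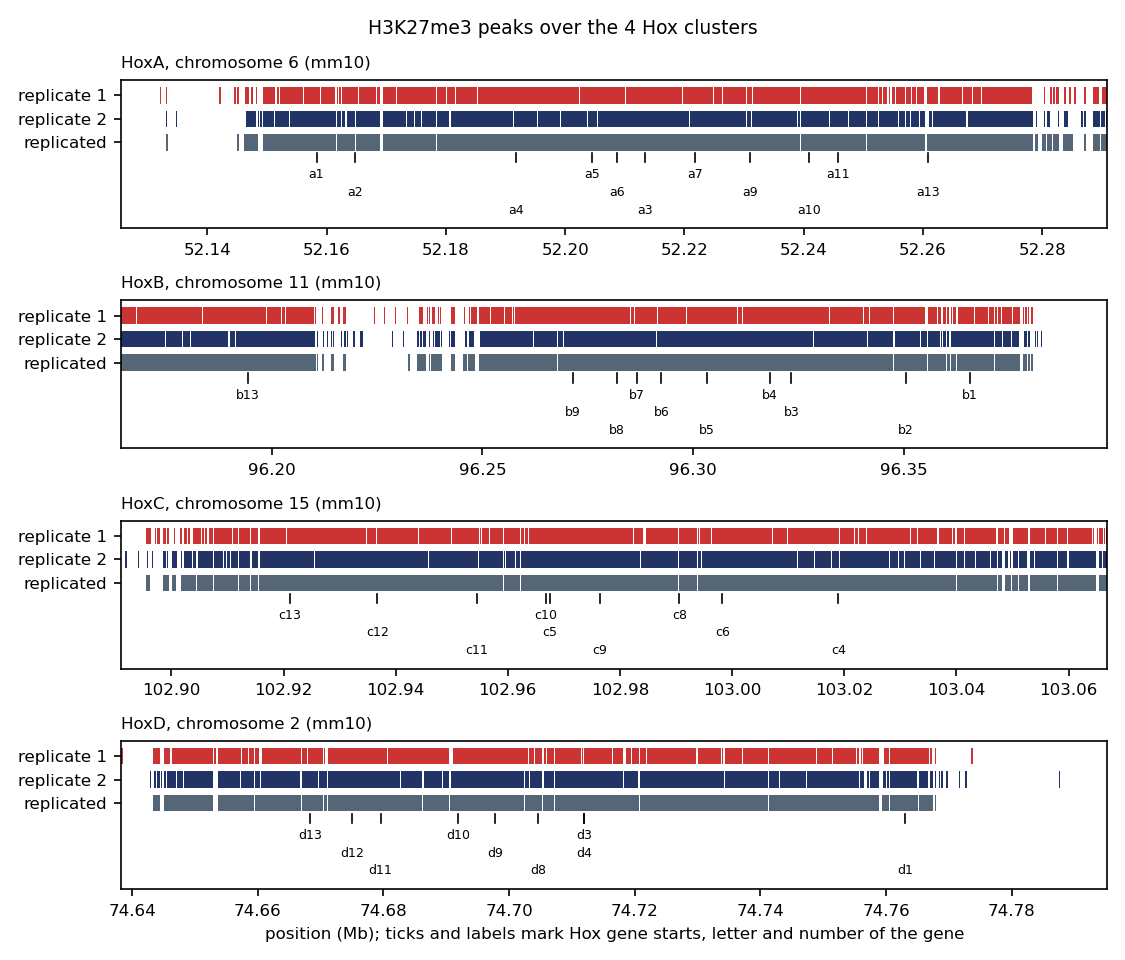
Peaks of replicate 1, replicate 2 and the replicated list over the 4 Hox clusters, with position in Mb (mm10) on the horizontal axis and the start of each Hox gene as a tick. Replicated peaks covered 98.2% of HoxA, 83.1% of HoxB, 99.2% of HoxC and 97.8% of HoxD, and the widest gap in HoxB lay between Hoxb13 and Hoxb9.

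Transcription factors of neural, endodermal, mesodermal, blood and muscle lineages were marked more often than other genes. Of 51 regulators of neural fate 49 were marked (96.1%; adjusted exact p = 1.58e-40). Sox1, a factor of neural progenitors, Neurod2, a neuronal factor, and Gbx2, which helps set the boundary between midbrain and hindbrain, had 99.5%, 99.3% and 99.2% of their 22 kb windows covered. Neurod4 and Neurod6 were the only members not marked by replicated peaks. Replicate 1 peaks marked 49 of the 51 and replicate 2 peaks 50. Of 26 endoderm regulators 21 were marked (80.8%; adjusted exact p = 1.61e-14), among them Cdx2, an intestinal factor, Mnx1 and Onecut2. Foxi1, Hnf1a and Hnf4a were not marked, with replicated peaks over 0.0% of each promoter window. Of 30 regulators of heart and trunk mesoderm 25 were marked (83.3%; adjusted exact p = 1.31e-17), led by the heart factor Nkx2-5, Uncx and Foxf1, while Hey1, Meox1 and Msgn1 were not. Blood regulators were marked in 15 of 27 cases (55.6%; adjusted exact p = 2.41e-07). Gata3, Pax5 and Gata2, which act in T cells, B cells and blood progenitors, were fully covered at their promoters, whereas Bcl11b and Cebpe were at 0.0% and Ebf1 at 10.6%. Of 16 skeletal muscle regulators 10 were marked (62.5%; adjusted exact p = 6.85e-06), with Lbx1, Pax7 and Pax3 the most broadly covered. Myf5, Eya1 and Mef2c were not. The Myf5 promoter was covered over 23.3% by replicated peaks and over 31.1 ± 3.11% by the replicates' peaks (SD, n = 2), on either side of the threshold.

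Regulators restricted to a region of the face were marked in 22 of 24 cases (91.7%; adjusted exact p = 1.5e-17). Nkx2-3, Dlx6, a regulator of lower jaw identity, and Foxf1 were fully covered at their promoters, with replicate values of 95.2 ± 6.79%, 86.0 ± 3.5% and 95.5 ± 0.283% (SD, n = 2). Regulators broadly used in face mesenchyme were marked in 17 of 30 cases (56.7%; adjusted exact p = 2.53e-08). Msx1, in which mutation causes cleft palate, Foxf2 and Foxc1 had 91.8%, 100% and 84.8% of their promoter windows covered. Alx4, Ets1 and Meis1 were not marked, at 14.2%, 24.8% and 0.0%. Ets1 lay just under the threshold, with replicate values of 24.4 ± 7.95% (SD, n = 2). The mesenchyme regulators were marked less often than the neural regulators (two-sided Fisher's exact adjusted p = 5.91e-05 over 6 comparisons between lists) and than the regional regulators (adjusted exact p = 0.00846). Among CpG-rich promoters alone the contrast with the neural regulators stayed, at 11 of 17 against 35 of 35 (p = 0.000608, Fisher's exact test). The contrast with the regional regulators did not pass there, at 11 of 17 against 13 of 14 (p = 0.094, Fisher's exact test).

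**Figure D2:**
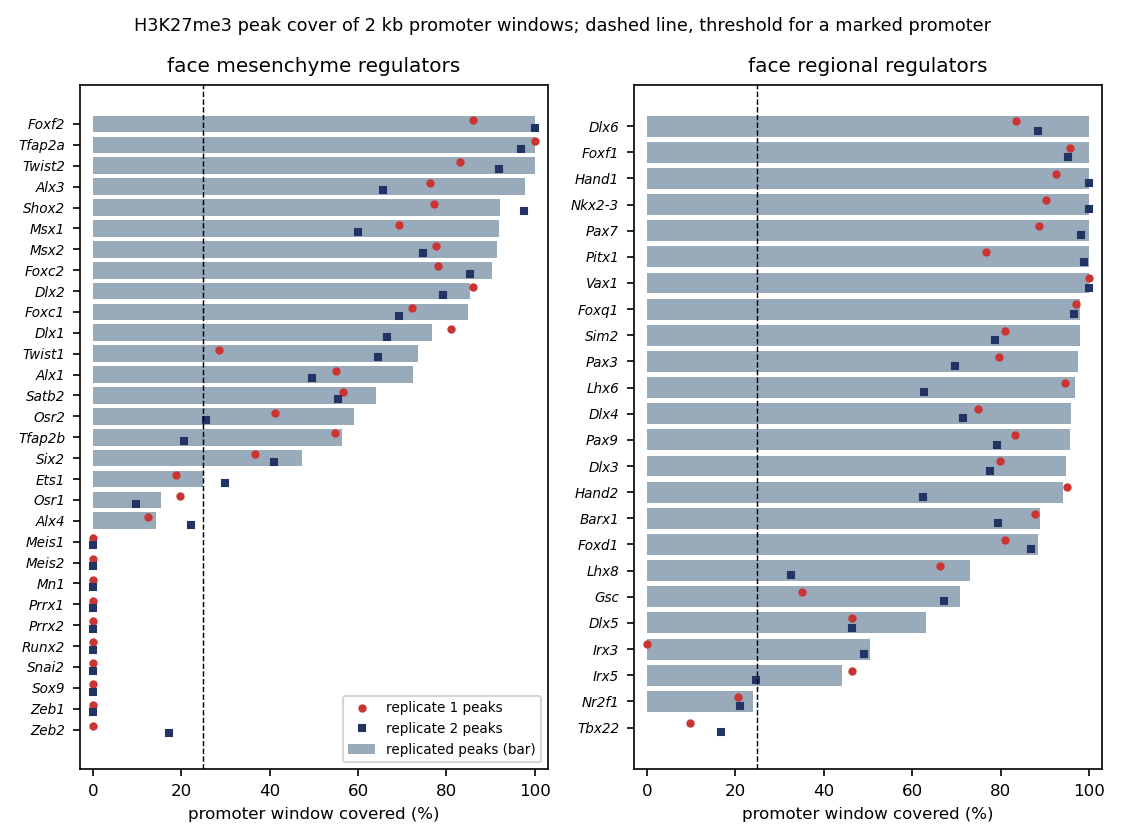
Percent of the 2 kb promoter window covered by replicated peaks (bars) and by the peaks of each replicate (points) for face mesenchyme regulators and face regional regulators. The dashed line is the 25% threshold, which 17 of 30 mesenchyme regulators and 22 of 24 regional regulators reached.

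Epithelial genes were marked in 20 of 26 cases (76.9%; adjusted exact p = 3.37e-13). Sox2, Wnt10a and Pitx2 were the most broadly covered, and Klf4, Krt14 and Krt15, of which the latter are basal keratins, were at 0.0%. Genes of cartilage and bone were marked in 10 of 26 cases (38.5%; adjusted exact p = 0.00117), with Ihh, a signal of growing cartilage, Dlx5 and Sox6 covered over 100%, 63.2% and 56.0% of their promoters. Bglap, Col11a1 and Col1a1, which encode osteocalcin and fibrillar collagen chains, were at 0.0% in the replicated list. The replicates' own peaks covered 14.7 ± 6.97% of the Col1a1 promoter (SD, n = 2). Matrix genes fell on both sides, as further members named after their values were seen show. Acan, Comp and Col2a1 were marked, at 100%, 100% and 70.2%, and Col1a2 and Col9a1 were at 0.0%. That list did not pass when 50% coverage was required (23.1%; adjusted exact p = 0.0522). Genes linked to cleft lip or palate were marked in 22 of 35 cases (62.9%; adjusted exact p = 1.22e-11), and 23 of the 35 were also members of another list. Pax9, Pax7 and Msx1 led that list, and Arhgap29, Fgf10 and Fgfr1 were at 0.0%. Wnt, FGF, BMP and hedgehog ligands and their antagonists were marked in 40 of 57 cases (70.2%; adjusted exact p = 1.09e-22). Wnt10a, Wnt1 and Ihh had 93.3%, 80.0% and 72.5% of their 22 kb windows covered, while Bmp2, Bmp5 and Fgf1 were at 0.55%, 0.0% and 0.0% of their promoters.

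Terminal genes of neurons, skeletal muscle, liver and blood were marked unevenly. Neuronal genes were marked in 16 of 25 cases (64.0%; adjusted exact p = 6.33e-09). They included Slc32a1, the vesicular GABA transporter, Chat, which makes acetylcholine, and Gad2, while Camk2a, Dbh and Dcx were not marked. Genes of differentiated skeletal muscle were marked in 4 of 22 cases (18.2%; adjusted exact p = 0.542). Acta1, Ckm and Des were marked, and Actn2, Chrna1 and Chrnd were at 0.0%. Liver products were marked in 0 of 25 cases (adjusted exact p = 0.0818), Afp, Ahsg and Alb among them. Terminal blood genes were marked in 0 of 23 cases (adjusted exact p = 0.125), with Aif1, Alas2 and Cd19 at 0.0%. With no member marked the share could not be lower, so lists of this size could not be called below other genes here. In each of 3 lineages regulators were marked more often than terminal genes, with adjusted exact p = 0.00097 for neurons, 0.00918 for muscle and 4.76e-05 for blood (two-sided Fisher's exact tests). Among CpG-rich promoters alone the neuron contrast was 35 of 35 against 6 of 8 (unadjusted exact p = 0.031). The muscle contrast did not pass there, at 4 of 5 against 1 of 2 (exact p = 1). With so few genes that test cannot decide whether CpG content accounts for the contrast. No terminal blood gene was CpG-rich.

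Housekeeping genes were marked in 0 of 35 cases, below the 12.7% of other genes (adjusted exact p = 0.0244). Actb, Actg1, Atp5b and Gapdh had no peak in their promoter windows in the replicated list or in either replicate. The call was lost when 50% coverage was required (adjusted exact p = 0.0597) and among CpG-rich promoters alone (adjusted exact p = 0.0533), with 0.0% marked in both. Polycomb subunits and H3K27 demethylases were marked in 5 of 32 cases (15.6%; adjusted exact p = 0.593). The core subunits Ezh2, Eed and Suz12 were at 0.0% in the replicated list and in both replicates, as was Aebp2, and Bmi1 and Cbx2 were at 4.4% and 4.5%. Cbx8, Epop and Cbx4 were covered over 28.0%, 95.9% and 29.7%, and Pcgf5 and Phf19 were also marked, named here after their values were seen. Cyclin-dependent kinase inhibitors were marked in 2 of 7 cases (28.6%; adjusted exact p = 0.244). These were Cdkn2a and Cdkn2b, both at 100%, with Cdkn1a at 3.4% and Cdkn1b and Cdkn1c at 0.0%. With any annotated start 57.1% of the inhibitors were marked (adjusted exact p = 0.0144). Genes of imprinted clusters were marked in 11 of 30 cases (36.7%; adjusted exact p = 0.00112). Grb10, Dio3 and Igf2 were marked, whereas Ddc, Igf2r and Cdkn1c were at 0.0%. Among CpG-rich promoters alone 4 of 10 imprinted genes (40.0%) were marked and the call was lost (adjusted exact p = 0.101).

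**Figure D3:**
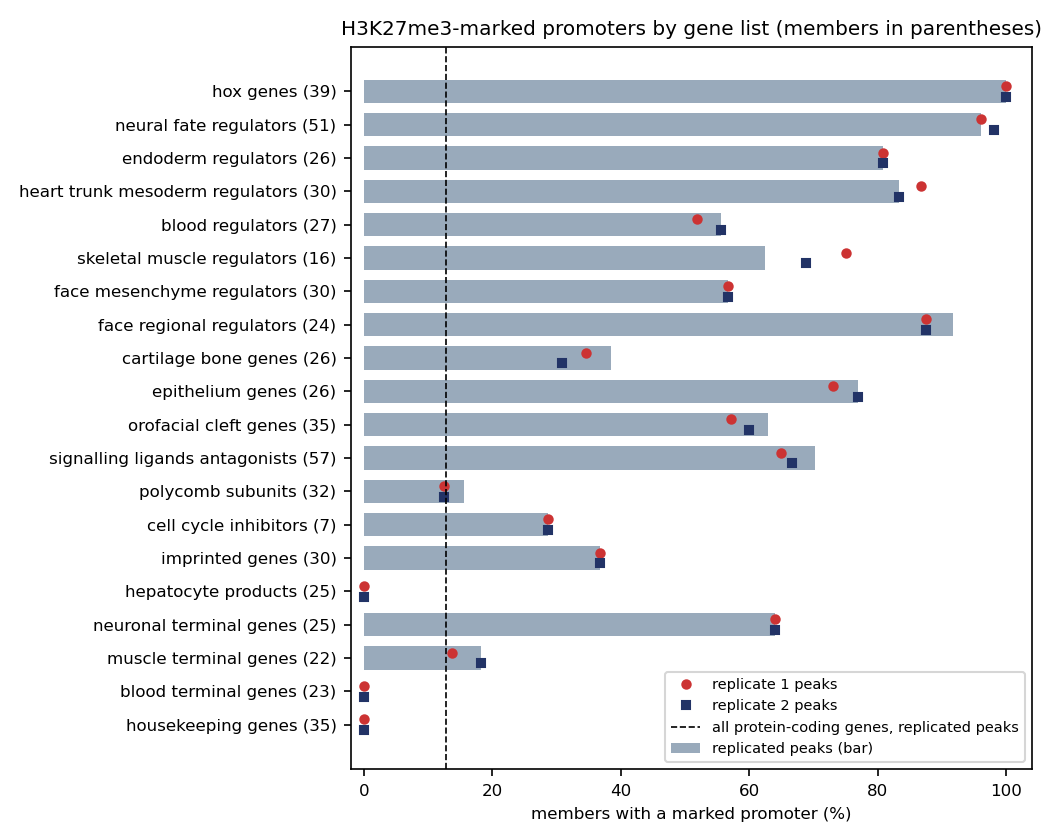
Percent of members with a marked promoter in each of 20 gene lists, for replicated peaks (bars) and the peaks of each replicate (points), with the number of members in parentheses. The dashed line is the 12.7% of all protein-coding genes, and the lists run from 0.0% of housekeeping genes to 100% of Hox genes.

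These list tests were two-sided Fisher's exact tests over genes, adjusted over 20 lists by the Benjamini-Hochberg method. Neighbouring genes such as those of a Hox cluster share peaks and are not independent, so the p-values describe the sets of genes and not the spread between embryos. For 11 lists none of 10000 random lists matched on promoter CpG content had as high a marked share. These were the lists of Hox genes, neural, endoderm, heart and trunk, blood, face mesenchyme and face regional regulators, epithelium, cleft, signalling and neuronal genes. Skeletal muscle regulators, cartilage and bone genes and imprinted genes lay above 99.99%, 99.91% and 99.87% of their matched lists. Imprinted genes were at 36.7%, beside a matched mean of 13.8%. Housekeeping genes, at 0.0%, lay below 99.84% of theirs, with a matched mean of 16.7%. Terminal muscle genes came highest among the remaining lists, above 89.59% of theirs.

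Replicated peaks joined at gaps of up to 5 kb made 8161 domains with a median width of 2212 bp, of which 306 were at least 20 kb wide. The widest 1% of domains, 82 in number, held 12.6% of called bases. The count of domains of at least 20 kb was 136 with gaps of up to 1 kb and 533 with gaps of up to 10 kb. With the peaks of replicate 1 alone there were 20376 domains, of which 534 were wide, and with those of replicate 2 alone 19228, of which 520 were wide. Hox clusters made 5 of the 10 widest. The widest spanned 223 kb with 9 HoxC genes (chromosome 15, 102895441 to 103118328). HoxA with Evx1 made a domain of 182 kb (chromosome 6, 52144984 to 52327241), and it also held the starts of 5730596B20Rik and Gm28308. Hoxb1 to Hoxb9 made one of 148 kb (chromosome 11, 96232387 to 96380809), and HoxD with Evx2 and Gm28230 one of 125 kb (chromosome 2, 74643387 to 74767995). Hoxb13 lay in a separate domain of 73.0 kb (chromosome 11, 96144662 to 96217668). Zic4 and Zic1, neighbouring factors of the neural tube and somites, shared 75.6 kb (chromosome 9, 91347364 to 91422937). A domain of 78.7 kb with no protein-coding start held Mir9-3 and its host transcript (chromosome 7, 79489755 to 79568470). The other 3 lay on chromosome X and were sparsely covered. They were 214 kb with Ribc1, Smc1a and Iqsec2 (152013281 to 152227006), 99.6 kb with Fam90a1b and Apoo (94302364 to 94401991) and 87.3 kb with no protein-coding start (167115853 to 167203138). Replicated peaks covered 43.2%, 40.5% and 26.5% of these, against 79.4% to 97.0% of the autosomal domains.

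The highest enrichment values, which are the authors' own value for each peak in the replicated list, were at Nrxn2, Nrg3, the HoxC cluster, Bhlhe23 and Nxph1. The peak with the highest value, 15.8, lay inside Nrxn2, a synaptic adhesion gene, 6816 bp from its start (chromosome 19, 6425547 to 6431618). Next came a peak of 14.2 over the start of Nrg3, a neuregulin gene (chromosome 14, 39470734 to 39477168). A peak of 13.9 covered the starts of Hoxc10, Hoxc5 and Hoxc9 (chromosome 15, 102962277 to 102984390). Bhlhe23, a neural transcription factor gene, had a peak of 13.5 (chromosome 2, 180774872 to 180779648), and Nxph1, which encodes a ligand of neurexins, one of 13.3 inside the gene (chromosome 6, 8955779 to 8958404).

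Chromosome X was more covered than any autosome. Replicated peaks covered 1.7% of X and 0.903% of the autosomes together, a ratio of 1.88, and the autosomes ranged from 0.431% for chromosome 16 to 1.6% for chromosome 19. The ratio was 2.4 with replicate 1 peaks and 2.03 with replicate 2 peaks, a mean of 2.21 ± 0.268 (SD, n = 2). It was 3.26 with pooled peaks, which covered 4.54% of X. No test was made of this ratio. No list held a peak on chromosome Y.

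**Figure D4:**
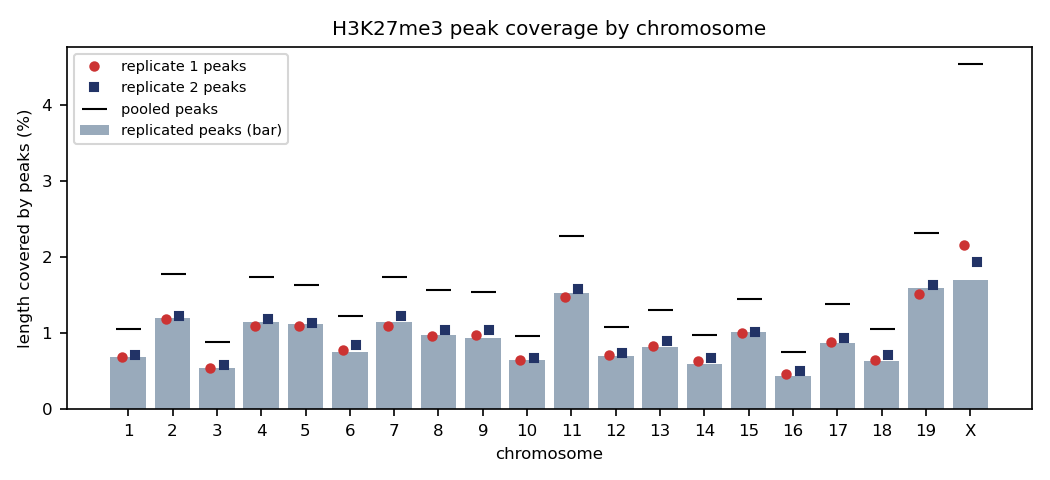
Percent of each chromosome's length covered by replicated peaks (bars), by the peaks of each replicate (points) and by pooled peaks (dashes). Chromosome X is the most covered in every list, with 1.7% of its length covered by replicated peaks and 4.54% by pooled peaks.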

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

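Requiring that replicated peaks also share 50% with a peak of both replicates was chosen after seeing the data; the other alternatives were planned. Of 250 alternative values, 228 kept their direction and their side of the threshold where there was a test, stayed within 1.5 times where they were counts, or moved by less than the spread between replicates where they were other values. The number of marked genes ranged from 2130 (50% coverage) to 3325 (any overlap), within 1.5 times of 2757, and was 2639 under the added alternative. Among pooled peaks with a −log10 q of at least 2, 40.4% were in the replicated list. With 50% coverage, cartilage and bone genes were no longer called (23.1%, adjusted exact p = 0.0522), nor were housekeeping genes (0.0%, adjusted exact p = 0.0597), and Polycomb subunits, called under neither setting, fell to 9.38%, below other genes. Among CpG-rich promoters alone, imprinted genes (40.0%, adjusted exact p = 0.101) and housekeeping genes (0.0%, adjusted exact p = 0.0533) were no longer called, with fewer genes tested. With any annotated start, cell cycle inhibitors (57.1%, adjusted exact p = 0.0144) and liver products (0.0%, adjusted exact p = 0.0491) became called, and with pooled peaks liver products (0.0%, adjusted exact p = 0.0496) and terminal blood genes (0.0%, adjusted exact p = 0.0487). Liver and blood genes had no marked member there or in the main setting, so these calls came from changes in other genes. The marked share of all genes was 12.7% in the main setting, 14.8% with any start and 14.9% with pooled peaks. In the main setting, random lists matched on CpG content had mean marked shares of 6.05% for liver products and 5.46% for terminal blood genes. The cause was not tested except where stated. Joining gaps of up to 1 kb gave 136 wide domains and 14.9% of called bases in the widest 1% of domains (119), and gaps of up to 10 kb gave 533 wide domains. Without replicate 1 or replicate 2, domains numbered 19228 to 20376, of which 520 to 534 were wide. The widest 1% of domains, 193 and 204 in number, held 17.2% and 18.8% of called bases. The ratio of X to autosomal coverage ranged from 2.03 to 2.4 with single replicates and was 3.26 with pooled peaks. Introns held 31.3% of pooled peak bases and were no longer called against shifts of the pooled peaks (permutation p = 0.0792). No paired analysis was possible because there was 1 group. Unknown depth leaves open whether an unmarked promoter lacks the mark or lies below what these libraries could detect.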

Other observations

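The gene prefixes, microRNA genes, the test of read depth, the tests of wide X domains in lists other than the pooled one, and the tests of CpG content and choice of start for face mesenchyme against regional regulators were chosen only after results were seen. Grouped by the first 3 letters of the symbol, with at least 15 genes per prefix, 27 of 231 prefixes had more marked promoters than other genes and 12 had fewer (two-sided Fisher's exact tests, Benjamini-Hochberg adjusted). No theme over prefixes was tested. Apart from Hox, the higher prefixes with the largest marked shares were Wnt with 16 of 19 genes (adjusted exact p = 1.11e-10), Htr, mostly serotonin receptors, with 14 of 18 (adjusted exact p = 1.67e-08), Sox with 12 of 19 (adjusted exact p = 8.35e-06), Pou with 10 of 16 (adjusted exact p = 7.31e-05) and Kcn, potassium channels, with 55 of 94 (adjusted exact p = 6.02e-24). Higher shares were also found for Mmp, matrix metalloproteinases, with 8 of 22, for Col, mostly collagens, with 15 of 52, and for Slc, solute carriers, with 77 of 385. Other prefixes of receptors and transcription factors did not pass, such as Gab with 8 of 30 (adjusted exact p = 0.169), Chr with 8 of 25 (adjusted exact p = 0.0563) and Klf with 4 of 17 (adjusted exact p = 0.4). The 12 lower prefixes were Olf, mostly olfactory receptors, with 4 of 1143 genes (adjusted exact p = 7.98e-60), Vmn, vomeronasal receptors, with 0 of 330 (adjusted exact p = 2.32e-18), Zfp, zinc finger proteins, with 16 of 397 (adjusted exact p = 1.3e-07), and Krt, Rpl, Btb, Def, Eif, His, Mrp, Tas and Wdr. Prefixes were not matched on CpG content. Among the lower ones the mean promoter CpG observed/expected ratio was 0.117 for Olf and 0.113 for Vmn, but 0.675 for Eif and 0.724 for His. Neighbouring genes of a prefix are not independent.

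MicroRNA genes lay inside replicated peaks in 83 of 2196 cases, of which 49 also lay inside peaks of both replicates, 10 of replicate 1 alone, 19 of replicate 2 alone and 5 of neither. In 100 circular shifts the mean was 21.2 and the highest 57 (one-sided permutation p = 0.0099, the smallest possible). No class of microRNA was tested. Those inside replicated peaks included Mir124a-1, Mir124a-2, Mir124a-3, Mir9-1, Mir9-2, Mir9-3 and Mir137, the genes Mir10a, Mir10b, Mir196a-1, Mir196a-2 and Mir196b of the Hox clusters, Mir290a, Mir290b, Mir291a, Mir291b and Mir293 of a single cluster, and Mir375, Mir203, Mir132 and Mir212. All of these lay inside peaks of both replicates except Mir9-2, which lay inside a replicate 1 peak alone, and Mir291b, inside a replicate 2 peak alone.

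Chromosome X was more covered than autosomes in every list. Without its 10 widest domains X stayed above chromosome 19, the most covered autosome, with pooled peaks (3.91% against 2.32%), replicate 1 peaks (1.95% against 1.52%) and replicate 2 peaks (1.8% against 1.64%), which argues against a few very wide domains there. With replicated peaks it fell to 1.53%, below the 1.6% of chromosome 19 but still 1.69 times the autosomes together, beside 1.88 with those domains. Most of the excess over the autosomes together in that list thus does not rest on the 10 widest domains. Chromosome 19 and the other autosomes kept their own widest domains. The comparison with chromosome 19 was therefore unequal and cannot show whether that margin rests on wide domains of X. A uniform offset of X against the control, through copy number, and the inactive X chromosome of the female embryos in both pools cannot be told apart here, with so few escaping genes, and both stay open. Pooled peaks covered a mean of 8.24% of the 22 kb windows of X genes known to be silenced on the inactive X. For autosomal housekeeping genes the mean was 0.467% (permutation p = 5e-05), a difference that both explanations allow. Coverage was above 0 at 19 of 33 silenced and 5 of 33 housekeeping genes. With replicated peaks the means were 3.81% and 0.249% (permutation p = 0.0173). The 2 sets were not matched on CpG content or kind of gene, so the difference may also rest on the choice of genes. With pooled peaks no difference between silenced genes and 6 genes known to escape silencing was detected (permutation p = 0.893).

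Face mesenchyme regulators were marked less often than neural and regional face regulators. Against neural regulators, promoter CpG content and the choice of start did not remove the difference, with p = 0.000608 among CpG-rich promoters and p = 0.000582 with any annotated start (Fisher's exact tests). Against regional regulators the choice of start did not remove it (exact p = 0.00134), but among CpG-rich promoters the shares of 64.7% and 92.9% no longer differed past the threshold (exact p = 0.094), where 17 and 14 genes were left from 30 and 24. The gap there was 28.2 points (95% interval −2.1 to 52.3, Newcombe), beside 35.0 (11.3 to 53.5) among all promoters, so the call ended with fewer genes while most of the gap stayed, and the interval is too wide to exclude CpG content for that part. A candidate explanation for the contrast with neural regulators is that mesenchyme regulators are in use in many of the cells sampled, which was not tested, since expression was not measured.

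The 3 smallest p-values of the replicated list did not belong to the peaks of highest enrichment value. The first 2 lay on an annotated ribosomal RNA gene (chromosome 17, 39843002 to 39846806 and 39847843 to 39848930), with −log10 p of 153 and 122 and enrichment values of 3.11 and 2.73, and the third inside Cdk8 (chromosome 5, 146260995 to 146261491), with 109 and 6.04. High read depth at repeated sequence may give such values, but read depth was not measured. Another peak of the same or a lower enrichment value reached at most 0.488 of their −log10 p, which restates how these peaks were picked and is no evidence on read depth. The Cdk8 peak was also not of low enrichment, at the 90.1 percentile.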
